A study of Mus musculus with 8 samples.

How the data were processed

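Copy number was measured on 8 Agilent 244K mouse comparative genomic hybridisation arrays, 1 per DNA sample. Per the labels, Cy5 carried the sample DNA and Cy3 carried DNA of a normal wild-type Balb/c mouse on every array. No dye swap was labelled. The samples were 3 primary T-lymphoblastic lymphomas (T-LBL), 1 primary myeloid hyperplasia and 4 secondary T-LBL whose names trace them to mouse 12. The replicate numbers run across different mice and do not pair them. The 4 secondary tumours share an origin with the primary tumour of mouse 12, so tests that treat the arrays as independent count related arrays as separate.

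The deposited array files hold processed signal intensities for both dyes. Per the file headers, Feature Extraction subtracted the background, removed a spatial trend and applied a linear dye normalisation to these intensities. The deposited LogRatio column and the deposited series table hold the same log10 values of processed Cy5 over processed Cy3. The median of these log10 values lay between −0.0009 and 0.0059 on the 8 arrays, and the value was set to 0 where neither channel was significant. Per the file headers, the software was version 10.5.1.1, while the labels name version 9.1.1. Probe positions are on mouse build mm9 in 7 files and on mm8 in the file of M12, so M12 took the mm9 positions of the other files by probe name. No coordinate was converted between builds.

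The log2 ratio of the processed signals was computed for each spot. Control spots and spots with an outlier flag were left out, spots of the same probe were averaged, and each array was centred on its autosomal median. This left 235402 probes, of which 221455 lay on autosomes, 11957 on chromosome X and 606 on chromosome Y. The remaining 346 probes on unplaced contigs or the mitochondrion and 1038 probes without a position were kept out of the comparisons. Autosomal probes had a median spacing of 7.82 kb and tiled 2414 Mb.

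For segmentation, values were winsorised at 3 SD around a running median of 11 probes. Each chromosome was segmented by exact penalised least squares with a penalty of 6 times the noise variance times the log of the probe number and at least 3 probes per segment. Neighbouring segments closer than 0.15 were merged. A segment was called at an absolute mean of 0.25 or more over at least 5 probes. Errors of values from a single array are standard errors over its probes, since no sample was hybridised again. A call of M12 counted as recovered in another array when calls in the same direction covered at least 50% of its probes, and 1000 random circular placements of the other array's calls gave the chance level.

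These choices, the comparisons, the naming rule and most alternatives were set before the data were examined. By the naming rule, each array's autosomal calls of 1 Mb or more (at most 15) and its 5 smaller calls with the largest absolute mean could be named. For each limma comparison and direction, up to 10 windows with an adjusted p under 0.05 could be named, if every array of the group had the same sign (or, between groups, if the groups did not overlap), with 1 window per run of neighbours. The following were chosen after the data were seen. Calls of different arrays were joined into regions when they overlapped or lay less than 150 kb apart, and the core of a region is the longest run covered by the most arrays. Regions whose core had under 75% of its probes well above background in the reference (median over arrays) were listed apart, and so were calls on X and Y. The 3 losses shared by the mouse 12 tumours were singled out. A log2 ratio in a region where a channel was dim was also bounded by raising that channel's dim probes to the lowest signal counted as well above background, and such folds are written as "at least".

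Group differences of regions and chromosomes were tested with a two-sided exact permutation test over all 35 splits of the 7 lymphoma arrays, whose smallest p is 0.0286, with Benjamini-Hochberg adjustment over 12 regions or 21 chromosomes. The files pair no probe with a gene, and the gene table at hand is on assembly GRCm38.p6, so means over windows of 10 consecutive probes took the place of genes. The 23390 windows, 22135 of them autosomal, were fitted in limma (lmFit and eBayes) with 3 groups over all 8 arrays. The contrasts were secondary against primary T-LBL, each lymphoma group against the reference, and primary T-LBL against the myeloid array, which was assumed to vary like the other groups. The adjusted p threshold was 0.05. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.

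Segmentation was tested on simulated data made by shuffling each array and implanting losses. It made 0 false calls on shuffled values. Shuffling removes runs of neighbouring probes that deviate together, so this count does not give the rate of false calls on the real arrays. On the 6 less noisy arrays it recovered 100% of losses of 60 probes at −0.5, 92.1% of losses of 10 probes at −1 and 0.877% of losses of 5 probes at −1. On M7 and M12.52 it recovered 100% of losses of 60 probes at −1 and 0% of losses of 60 probes at −0.5. In simulated windows for secondary against primary T-LBL, limma recovered 71.5% of 200 shifts of 0.5 with 3 false calls, 100% of shifts of 1 with 7 false calls, and 0% of shifts of 0.25. Against the reference it recovered 100% of shifts of 0.5 in the secondary group and 0% of shifts of 0.25. The simulated noise was drawn independently for each window, with the same SD for all windows of an array and no noise for M10. It was simpler than that of the data, so these rates need not hold there.

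The file headers gave 5 slides and 4 scans. The arrays M7, M9 and M12.52 were each on a slide that had carried another array before. M9 followed M12.50 on slide 3, M7 followed M10 on slide 4 and M12.52 followed M12.53 on slide 2. Differences were recomputed within scan 3 and slide 3, which held lymphomas of both groups. Scan was also used as a block in limma.

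The alternatives for the processing were call thresholds of 0.15 and 0.4, 3 or 10 probes per call, penalties of 3 and 12 times, no winsorising, normexp (offset 50) on the median and background signals, the series table, centring on the mode, probes well above background in the reference on every array, and subtraction of the myeloid array. The normexp offset is added to both dyes and draws ratios towards no change, most where signals are dim. Recovery was also recomputed with 80% cover, reciprocal cover, both breakpoints within 3 probes, and without calls of M12 that the myeloid array also holds. In limma, only the arrays of a comparison, origin as a random block, scan as a block and each probe on its own were also tried, and each replicate was left out in turn. Alternatives chosen after the data were seen were a correction for local probe density, M12.53 with its sign turned, leaving out the 3 arrays on re-used slides, array weights, slide as a random block, windows of 5 probes and recovery without the chromosome 3 call of M12. Not run were the regression on probe GC content, the values of the fixed receptor loci and fixed gene list, and the comparison of Jak2 and Sec31a exon with intron probes, since each needs a genome or annotation of build mm9.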

Results

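The data were copy number profiles of 8 DNA samples from mice carrying SEC31A-JAK2, a fusion that includes the tyrosine kinase JAK2, after bone marrow transplantation. The 3 primary T-lymphoblastic lymphomas (T-LBL) were M7 and M9 from spleen (replicates 1 and 2) and M12 from a neck lymph node (replicate 3). The 1 myeloid hyperplasia was M10, from bone marrow. The 4 secondary T-LBL traced to mouse 12 were M12.49 from pancreas, M12.50 from a neck lymph node, and M12.52 and M12.53 from pancreas (replicates 1 to 4). Each DNA was set against normal wild-type Balb/c DNA, and a negative log2 ratio stands for less DNA in the sample than in that reference. Positions are on mouse build mm9, and the files name no genes.

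The noise of the log2 ratio between neighbouring probes was 0.47 (SD) on M7 and 0.43 on M12.52, and between 0.22 and 0.28 on the other 6 arrays. On M7, 53.8% of the reference spots were well above background, against at least 98.4% on the other arrays. The number of arrays limits the precision of every group value. Each tumour was hybridised on 1 array, so values of single arrays carry the standard error over probes and no replicate error.

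The first comparison asked where each tumour genome departed from normal DNA. Few autosomal copy number changes were called in the lymphomas, and the called changes were focal. Most of those measured in regions with good reference signal were losses. Shallow or short changes could be missed. In simulated data, 0% of losses of 60 probes at −0.5 were recovered on M7 and M12.52. Losses of 10 probes at −0.5 were recovered at 0% on the less noisy arrays too. A loss on chromosome 14 was called in all 7 lymphomas, and losses on chromosomes 6 and 12 were called in the 5 tumours of the mouse 12 lineage. The myeloid hyperplasia had none of these losses.

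Autosomal calls numbered 3 in M7, 9 in M9, 7 in M12 and 1 in M10. The secondary tumours had 15 in M12.49 and 7 each in M12.50, M12.52 and M12.53. The mean was 6.33 ± 3.06 calls in primary T-LBL (SD, n = 3) and 9 ± 4 in secondary T-LBL (SD, n = 4). Calls covered 3.95 ± 1.96 Mb of the autosomes in primary T-LBL (SD, n = 3) and 5.84 ± 1.30 Mb in secondary T-LBL (SD, n = 4), or 0.164% and 0.242% of the tiled length. The order of the groups depended on the settings. The shares were 0.0644% and 0.184% with probes well above background in the reference, but 0.270% and 0.242% at a call threshold of 0.15, 0.317% and 0.256% with the penalty of 3 times, and 0.257% and 0.234% without arrays on re-used slides. In M10 they covered 0.385 Mb. Of all 56 autosomal calls, 20 lay in 6 regions of chromosomes 3, 4, 11 and 19 where the reference signal, as the median over arrays, was near background. The 1 call of M12 among them, on chromosome 3, had 100% of its reference probes well above background. Of the other 36 calls, 34 were losses, with neighbouring segments of the chromosome 14 region in the mouse 12 lineage counted as separate calls.

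The chromosome 14 losses spanned 53201304 to 54837072 in the lymphomas together. Their core, 54337752 to 54763495 (426 kb, 59 probes), had a mean log2 ratio of −0.74 ± 0.09 in M7 and −0.51 ± 0.05 in M9. The core fell further in the mouse 12 lineage, to −2.45 ± 0.13 in M12, −2.93 ± 0.13 in M12.49, −3.26 ± 0.17 in M12.50, −3.01 ± 0.14 in M12.52 and −2.59 ± 0.17 in M12.53. It measured −0.07 ± 0.03 in M10. Many sample signals in the core were too dim in the lineage for an exact ratio. The reference exceeded the sample there at least 4.37-fold in M12.52 and at least 7.57-fold in M12.50, with the bounds of the other 3 lineage arrays in between.

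**Figure D1:**
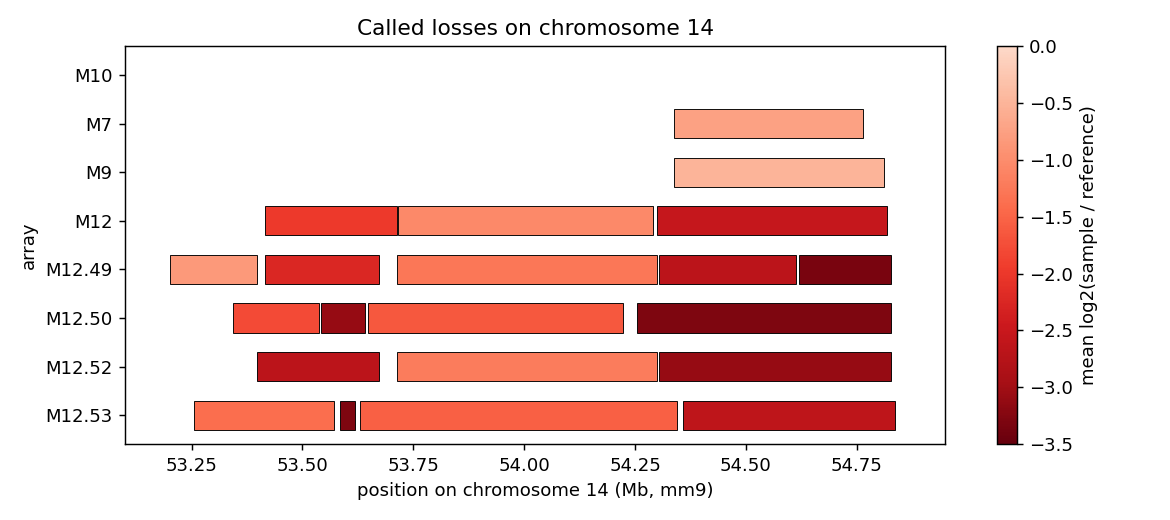
Called losses on chromosome 14 along its mm9 position (Mb), with 1 line per array and the mean log2 ratio of each call as colour. M7 and M9 have a single call over the core, the 5 arrays of the mouse 12 lineage have deeper calls that start further left, and M10 has none.

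The chromosome 6 loss ran from 41018389 to 41489670 (471 kb, 60 probes), with the same ends in all 5 tumours of the mouse 12 lineage. Its mean was −0.63 ± 0.06 in M12, −0.92 ± 0.08 in M12.49, −0.92 ± 0.08 in M12.50, −1.07 ± 0.09 in M12.52 and −0.99 ± 0.06 in M12.53. The same 60 probes averaged −0.46 ± 0.09 in M7 and −0.30 ± 0.04 in M9, where no segment was called, and 0.06 ± 0.04 in M10. The chromosome 12 loss spanned 107329523 to 109293982 (1964 kb, 103 probes). It measured −0.64 ± 0.03 in M12, −0.76 ± 0.03 in M12.49, −0.94 ± 0.03 in M12.50, −0.71 ± 0.04 in M12.52 and −0.79 ± 0.03 in M12.53. Outside the lineage it was near 0, at 0.07 ± 0.05 in M7, −0.00 ± 0.02 in M9 and −0.10 ± 0.03 in M10.

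**Figure D2:**
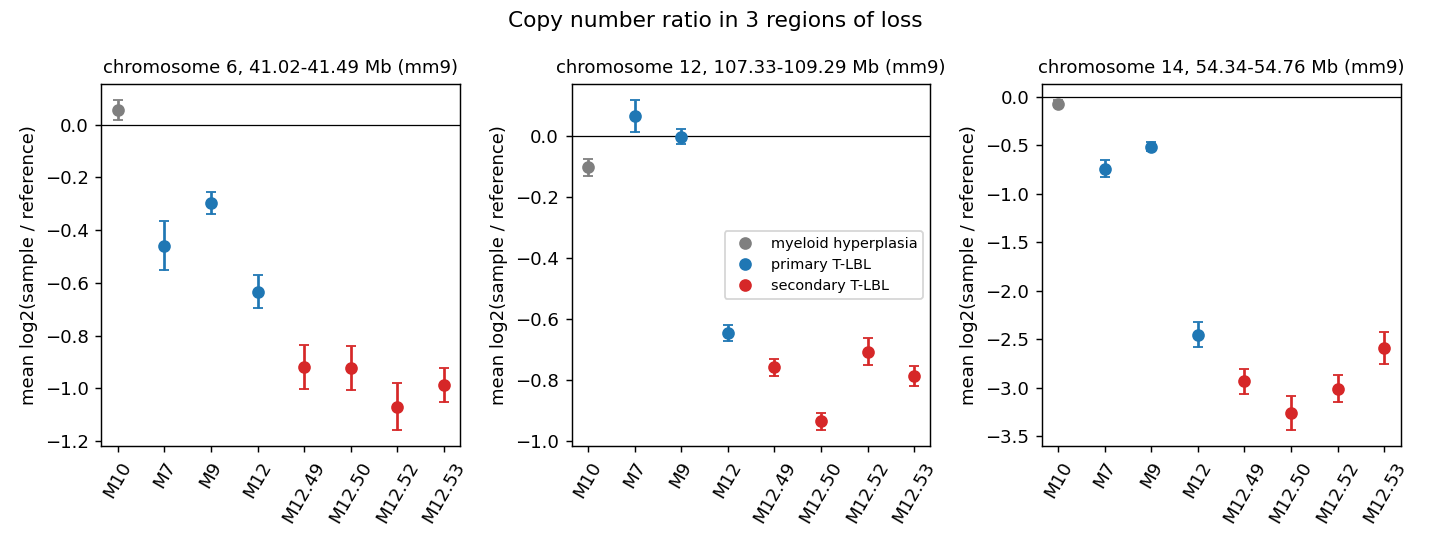
Mean log2 ratio of sample over reference in 3 regions for each array, coloured by group, with bars for the standard error over probes. All 7 lymphomas lie below M10 on chromosomes 6 and 14, while on chromosome 12 M12 and the 4 secondary tumours lie at −0.64 or lower and the other 3 arrays at −0.10 or higher.

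Further calls in regions with good reference signal were carried by 1 or 2 arrays. M12.49 alone had a loss on chromosome 6 from 8333534 to 8458778 (19 probes), at −1.09 ± 0.05, while the other 7 arrays lay between −0.20 and 0.27. With normexp signals this value was −0.09. A short loss on chromosome 12 from 114670169 to 114713534 (5 probes) was called in M12.49 and M12.50. With dim sample probes its size is a bound, and the reference exceeded the sample at least 3.76-fold in M12.49 and 3.70-fold in M12.50. Uncalled, it did so at least 2.82-fold in M12.52 and 2.10-fold in M9. The same 5 probes measured −0.37 ± 0.26 in M12.53, −0.33 ± 0.06 in M10, −0.15 ± 0.20 in M12 and, over 4 probes, 0.30 ± 0.06 in M7. A gain on chromosome 10 from 79059568 to 80764528 measured 0.26 ± 0.01 in M12 and 0.45 ± 0.02 in M12.53. The M12 value lay near the call threshold of 0.25, and it was 0.19 after the density correction and 0.23 with probes well above background in the reference. M12 was not called there in these 2 alternatives, with centring on the mode or at a threshold of 0.4.

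Among the regions with dim reference signal, the chromosome 3 core from 44188385 to 44493400 (15 probes) split the mice. The sample exceeded the reference at least 14.9-fold in M10, 12.6-fold in M9 and 2.41-fold in M7. In M12 the reference exceeded the sample at least 10.3-fold, with a deviation of 4.48 in its reference dye and −0.33 in its sample dye. In the 4 secondary tumours the measured log2 ratio lay between 0.51 and 2.08, with 13.3% or fewer of the reference probes above background.

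The second comparison asked whether the secondary tumours kept the changes of the primary tumour of mouse 12. They kept most of them. All 4 secondary tumours carried the 5 loss segments that M12 had on chromosomes 6, 12 and 14. Those on chromosome 14 are neighbouring segments of the same region, which the shares below therefore count more than once. The M12 gain on chromosome 10 recurred in M12.53 alone, and the chromosome 3 call of M12 recurred in none. That call rests on the reference dye of M12, since its sample dye, at −0.33, lay within the range of the secondary tumours, −1.54 to −0.00.

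Of the 7 autosomal calls of M12, 5 (71.4%) were recovered in M12.49, M12.50 and M12.52 each, and 6 (85.7%) in M12.53, a mean of 75% ± 7.14 (SD, n = 4). Without the chromosome 3 call of M12 the shares were 83.3% in those 3 and 100% in M12.53, a mean of 87.5%. The call that M12.53 recovered beyond the other secondary tumours is the chromosome 10 gain, whose M12 value lay near the threshold. M7 and M9 recovered 1 each (14.3%), on chromosome 14, and M10 recovered 0. The mean share of M7 and M9 was 40% with probes well above background in the reference, 33.3% without winsorising, 30% with the penalty of 3 times and 0% with normexp signals. Random placement of the calls recovered a mean of at most 0.007 of the 7 calls, and at most 3. Both breakpoints lay within 3 probes for 4 calls in M12.49, M12.50 and M12.52 and for 2 calls in M12.53. The secondary mean lay below M12 by a log2 difference of −0.34 on chromosome 6 and −0.15 on chromosome 12. On chromosome 14 too many sample probes were dim to order M12 and the secondary tumours, with 13.6% above background in M12.52 and 27.1% in M12.49. On the M12 array the reference signal itself was lower than usual in 2 of these regions, with a deviation of −0.23 ± 0.04 on chromosome 6 and −0.38 ± 0.05 on chromosome 14, and 0.04 ± 0.03 on chromosome 12.

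The third comparison set the secondary against the primary lymphomas. The mean log2 ratio was lower in the secondary than in the primary tumours in the 3 regions of the mouse 12 lineage. None of the differences passed the correction for multiple tests. By log2 ratio each secondary array lay below each primary array in all 3 regions. In the sample dye alone M12 was lower than M12.49 on chromosome 6, and lower than M12.49 and M12.53 on chromosome 14, so the ranking against M12 rests partly on its reference dye, and on chromosome 14 also on dim sample probes. On chromosomes 12 and 14, M12 lay closer to the secondary tumours than to M7 and M9. Organ also differed, with M7 and M9 from spleen, M12 and M12.50 from neck lymph node, and M12.49, M12.52 and M12.53 from pancreas. The share of tumour cells in each DNA, which also scales the log2 ratio of a loss, was not given. Organ and tumour cell share can therefore not be told apart from transplant stage in these differences.

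On chromosome 6 the mean was −0.46 ± 0.17 in primary and −0.97 ± 0.07 in secondary T-LBL (SD), a difference of −0.51. On chromosome 12 it was −0.19 ± 0.39 and −0.80 ± 0.10, a difference of −0.60, and on chromosome 14 it was −1.24 ± 1.06 and −2.95 ± 0.28, a difference of −1.71. The chromosome 14 sizes are not exact, since many sample probes of the mouse 12 lineage were dim there. With normexp signals the primary and secondary means were −0.19 and −0.49 on chromosome 6, −0.07 and −0.43 on chromosome 12, and −0.37 and −0.85 on chromosome 14. Each of the 3 differences had an exact permutation p of 0.0286 (two-sided, n = 3 and n = 4), the smallest that 35 splits allow, and an adjusted p of 0.114 over 12 regions. These regions were singled out because M12 and the secondary arrays were called lost there, so a lower secondary mean was partly built in. The 4 secondary tumours and M12 also share an origin, so the splits do not exchange independent arrays. The p-values are therefore no independent support. Over the alternatives the adjusted p ranged from 0.0686 to 1. Within scan 3, M12.49 and M12.52 differed from M9 by −0.70 on chromosome 6, −0.73 on chromosome 12 and −2.46 on chromosome 14. On slide 3, M12.50 differed from M9 by −0.63, −0.93 and −2.75 in the same order. The other scans and slides held no lymphomas of both groups.

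Across the genome, limma called 0 autosomal windows between secondary and primary T-LBL, with 249 windows at an unadjusted p under 0.05. Without M12 it called 23 windows, all in the 3 shared losses and all lower in secondary T-LBL. Those regions were chosen from calls of these same secondary arrays, so the overlap is no independent support. With scan as a block it called 30, of which 26 lay in the shared losses, but only scan 3 holds both groups, so that fit sets M9 alone against M12.49 and M12.52 with 2 residual degrees of freedom.

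The fourth comparison tested each lymphoma group against the reference. In the main fit the windows called in the secondary tumours were lower than normal DNA, and 22 of the 23 lay in the shared losses. Those regions were chosen because these same arrays were called lost there, so the overlap is no independent support. Shifts of 0.25 were not recovered in simulated windows, whose noise was simpler than that of the data. Of the 12 windows that overlap the chromosome 12 region, 5 were called, though its secondary mean was −0.80. Changes larger than 0.25 elsewhere could therefore be missed too. The primary tumours, which came from 3 mice, had no window past the threshold. In the secondary group limma called 23 autosomal windows, all lower, with 873 at an unadjusted p under 0.05. Of the 23, 11 lay in the chromosome 14 region, 6 in the chromosome 6 region, 5 in the chromosome 12 region and 1 on chromosome 13. Leaving out 1 array lowered the count to 8 without M12.49, 5 without M12.50, 6 without M12.52 and 6 without M12.53, each time all in the shared losses. With origin as a random block, 3 windows passed the threshold, all in the shared losses. All 4 secondary tumours descend from mouse 12, so this fit cannot supply a spread between origins for the group. It therefore does not show that the 3 windows would hold in tumours of other mice. With array weights limma called 9103 windows, 3442 higher and 5661 lower, of which 32 lay in the shared losses. After subtraction of M10 it called 94, 20 higher and 74 lower, of which 30 lay there. With normexp signals limma called 0 windows, with 2015 at an unadjusted p under 0.05. The normexp offset of 50 in both dyes draws ratios towards 0. The median net reference signal was 105 on M12.49, 130.5 on M12.50, 104 on M12.52 and 68 on M12.53. Whether the offset accounts for the 0 called windows was not tested, and limma's windows at an unadjusted p under 0.05 rose from 873 to 2015.

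The lowest value was on chromosome 14 from 54683914 to 54746960, where limma's log2 value was −3.52 ± 0.27 (SE, adjusted p 0.00174, from 6.27e-19 to 0.431 over 17 alternatives, past the threshold in 14). Its size is not exact, since 0% of its sample probes in M12.52 and 10% in M12.49 were above background. On chromosome 6 from 41205049 to 41260280 it was −1.04 ± 0.06 (SE, limma adjusted p 8.53e-04, from 6.20e-12 to 0.494, past the threshold in 15 of 17). On chromosome 12 from 109177424 to 109226058 it was −0.87 ± 0.10 (SE, limma adjusted p 0.0152, from 1.32e-10 to 1, past the threshold in 10 of 17). The other named windows on chromosome 12 began at 107730275, with a value of −0.76 (limma adjusted p 0.0401, from 2.06e-10 to 1), and at 107310073, with −0.63 (limma adjusted p 0.0331, from 6.32e-08 to 1). Both passed the threshold in 9 of 17 alternatives. All 4 secondary arrays were below 0 in each of these windows. The chromosome 13 window from 19253466 to 19380346 measured −0.73 ± 0.10 (SE, limma adjusted p 0.0442, from 1.15e-08 to 1) and passed the threshold in 7 of 17 alternatives. Its loss was uneven over its 10 probes, with a standard error over probes between 0.38 and 0.53 in the 4 secondary arrays. The same window measured −0.61 ± 0.42 in M12, −0.32 ± 0.26 in M9, 0.11 ± 0.19 in M7 and 0.09 ± 0.04 in M10.

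In primary T-LBL against the reference, limma called 0 autosomal windows, with 634 at an unadjusted p under 0.05. Without M9 it called 5, all lower and in the shared losses. After subtraction of M10, which puts the noise of that array into every other, it called 371. Of these, 212 were higher, 159 lower and 7 in the shared losses.

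The fifth comparison set the primary lymphomas against the myeloid hyperplasia of the same transplant model. The 3 lymphomas measured lower than the myeloid sample on chromosomes 6 and 14. The single myeloid array gives no spread between animals, so these differences were not shown to exceed it. By limma's test, which borrows the spread of the other groups, no difference passed the threshold. It called 0 autosomal windows, and 106 had an unadjusted p under 0.05. Without M9 it called 4 and without M12 it called 2, all lower and in the shared losses. With scan as a block it called 12, of which 4 were higher, 8 lower and 0 in the shared losses, with 1952 at an unadjusted p under 0.05. That fit links M9 and M10 through the secondary arrays of their scans, with 2 residual degrees of freedom. Beside the autosomal windows, windows on X were called without M9, without M12 and with scan as a block. Windows on Y were called in the latter pair.

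Whole autosomes were balanced. The mean log2 ratio of an autosome lay between −0.06 and 0.09 in every array. Of 21 chromosomes tested between secondary and primary T-LBL by the exact permutation test, 0 passed the adjusted threshold and 0 had an unadjusted p under 0.05.

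The sex chromosomes set 2 arrays apart. In M12 the mean log2 ratio was −0.90 on X and 2.88 on Y. In M10 it was 0.83 on X and −1.86 on Y. These sizes are not exact. With normexp signals the values were −0.43 and 0.15 in M12 and 0.56 and −0.58 in M10, and with probes well above background in the reference the Y values were 1.70 and −0.98. In the other 6 arrays it lay between −0.11 and 0.29 on X and between −0.35 and 0.06 on Y. The highest X value of the 6 was that of M9. Each dye was also read on its own, as the deviation from each probe's median over all 8 arrays. In M12 the reference dye deviated by 0.82 on X and by −3.14 on Y, and the sample dye by −0.17 and −0.03. In M10 the sample dye deviated by 0.66 on X and by −1.84 on Y, and the reference dye by −0.07 and 0.04.

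**Figure D3:**
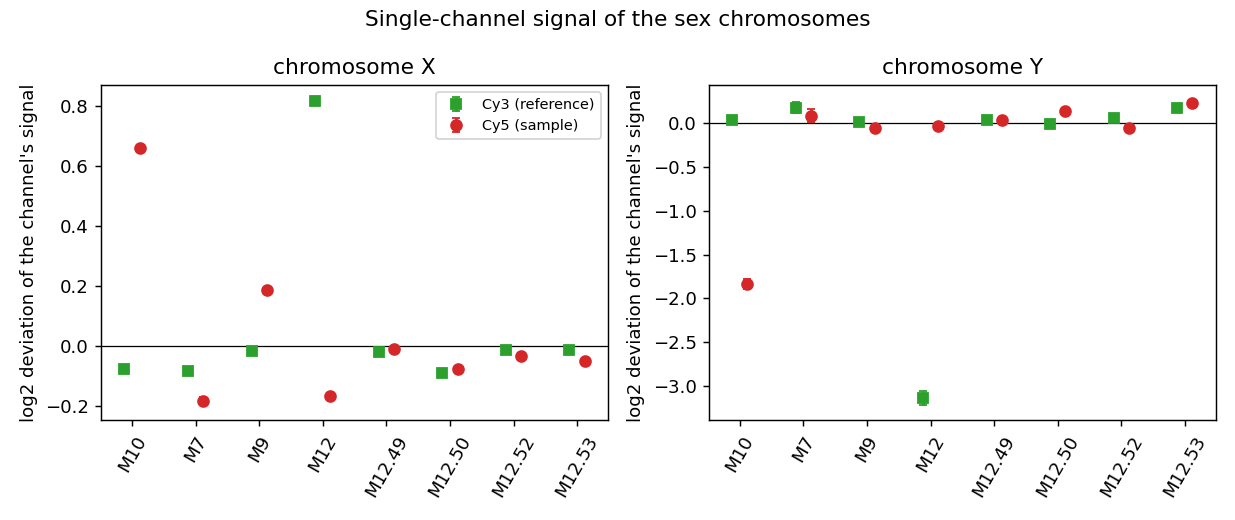
Median log2 deviation of each dye's signal on chromosomes X and Y for each array, with bars for the standard error over probes. The reference dye of M12 and the sample dye of M10 stand apart from the other arrays, at −3.14 and −1.84 on Y.

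The labelled dye direction was kept for all 8 arrays. Over the autosomal probes, M12.53 correlated below 0 with M10 (Pearson r = −0.46), M12 (−0.44), M12.49 (−0.40), M12.50 (−0.32), M12.52 (−0.51) and M9 (−0.21), across probes, which are not independent replicates. With M7 it correlated at 0.10, and M7 correlated below 0 with the other 6 arrays, from −0.25 to −0.11. Over the 222 probes of the 3 shared losses it correlated at 0.85 with M12, 0.78 with M12.49, 0.91 with M12.50 and 0.73 with M12.52. These probes were chosen because the lineage, M12.53 included, was called lost there. The dyes read on their own place the loss in its labelled sample dye. Most of the 8 arrays carry the deep chromosome 14 loss, so a sample dye near the median over arrays stands there for the lost state. In the chromosome 14 core that dye deviated by −0.01 ± 0.11 in M12.53, from −0.62 to −0.29 in the other 4 lineage arrays and by 2.54 in M10, while the reference dye of M12.53 deviated by 0.09 ± 0.10. With its sign turned, the chromosome 10 gain of M12.53 became −0.45, the mean share of recovered M12 calls became 53.6%, and limma called 0 windows in secondary T-LBL against the reference, with 3173 at an unadjusted p under 0.05.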

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

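All tests of explanations in this part were chosen after their results were seen, except the test of the brightest chromosome Y probes, whose outcome had been set down before.

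Among the 4 secondary tumours, M12.49 stood apart in its number of autosomal calls, with 15 against 7 in each of the others. M12.53 stood apart in the share of M12 calls it recovered, at 85.7% against 71.4%. Of 37 values tested among the 4 arrays, 2 stood apart, where chance alone gives about 1 in 20. In both, the other arrays were tied, so any difference would have stood apart and this rate does not hold for them. Of the 15 calls of M12.49, 6 lay in regions of dim reference signal, and those on chromosome 14 are neighbouring segments of the same region. Probes of an unplaced contig of chromosome X, used in no comparison, had a log2 ratio of −0.78 in M12, below the 0.68 of the myeloid array M10.

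The first pattern is the M12 array, whose log2 ratios ran against those of its own secondary tumours on X, on Y and in the chromosome 3 region. A change in the M12 sample DNA is argued against by its own dye, since the Cy5 deviation on Y differed from the secondary arrays by −0.11. The reference dye carried the difference, with a Cy3 deviation of −3.14 on Y against −0.01 to 0.17 on the other 7 arrays, and a deviation of 4.48 in the chromosome 3 core. Another reference DNA on this array, from a mouse without chromosome Y and of another strain or substrain, is a candidate explanation for all 3 places. M12 ratios on X, Y and chromosome 3 may therefore describe the reference, and no biological explanation beyond the sample DNA was tested.

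The second pattern is the myeloid array M10, with more X and less Y signal in the sample dye. Loss of Y alone is argued against by the Cy5 deviation of 0.66 on X. DNA without any Y, its signal held up by background on a dim array, stays open, since over the 152 brightest Y probes M10 lay 0.95 above the M12 reference dye (−0.72 ± 0.10 against −1.67 ± 0.17). A mixture of DNA with and without Y, as host and donor cells of a transplant could give, also stays open. Both shares without Y were scaled to the reference dye of M12, taken as DNA without Y, which is itself only a candidate. On that scale the share was 76.5% from all X probes and 57.4% from the 152 brightest Y probes, 19.1 percentage points apart. Another scale would change the shares and their gap. The labels give no sex for donor or recipient.

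The third pattern is the chromosome 14 loss called in all 7 lymphomas and not in the myeloid array, with a chromosome 6 loss called in 5 of them and, uncalled, mean values of −0.46 in M7 and −0.30 in M9. Carry-over from M12.50 on the re-used slide of M9 would need a share of 33.5% and predicts −0.25 on chromosome 12, where M9 measured −0.00 ± 0.02. Admixture of the mouse 12 lineage in M7 would need 49.1% and predicts −0.28 there, where M7 measured 0.07 ± 0.05. Rearrangement of T-cell receptor genes, which lie on chromosomes 6, 13 and 14, is a candidate biological explanation. All 7 lymphomas had the chromosome 14 loss, the smallest at −0.51, but rearrangement cannot be told apart from other losses here, since the receptor loci could not be placed on the build of the files.

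For the count of windows that limma called between secondary and primary T-LBL, the real split gave 0, so all 35 of 35 splits of the 7 lymphomas must give at least as many, and the comparison says nothing about chance. The highest other split also gave 0. At an unadjusted p under 0.05 the real split gave 249 windows, 22 splits gave as many or more, and the highest gave 4050.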

How the results depend on the processing

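The alternatives with M12.53 turned, without arrays on re-used slides, with array weights, with windows of 5 probes, with a density correction and without the chromosome 3 call of M12 were chosen after the data were seen. Of 482 values under alternatives, 1 changed direction. That was the chromosome 10 gain of M12.53, at −0.45 with its sign turned, which follows from the turn itself. Of 213 values that answer a comparison, 174 kept their direction and their side of the threshold or, untested, moved less than their spread (counts, by less than 1.5 times). For the exact tests of regions and whole chromosomes the side of the threshold could hardly change, so only their direction counts here.

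The differences between secondary and primary T-LBL kept their direction under all 16 alternatives, from −0.77 to −0.02 on chromosome 6, from −0.83 to −0.18 on chromosome 12 and from −2.32 to −0.42 on chromosome 14. With any array left out the exact test has too few splits to pass the threshold.

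The mean number of calls in primary T-LBL, 6.33, was 3.33 with normexp signals, 2.33 with probes well above background in the reference and 13.3 with the penalty of 3 times. In secondary T-LBL, 9 became 5.75 and 14.8 under the latter pair. In M10, 1 became 2, 0 and 3 in that order. The background filter by construction removes probes of the dim regions, which held 20 of 56 calls. The other causes were not tested.

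The mean share of M12 calls recovered, 75%, was 53.6% with M12.53 turned, 50% with both breakpoints within 3 probes or with normexp signals, 65.6% at a threshold of 0.15, 63.5% after subtraction of M10, and 83.3% at a threshold of 0.4, with centring on the mode or with the density correction. It was 100% with the background filter and 87.5% without the chromosome 3 call. The cause of these shifts was not tested.

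By limma, secondary against primary T-LBL gave 0 windows, 30 with scan as a block and 83 without arrays on re-used slides. Leaving out 1 array gave 0 to 23, the highest without M12. Primary T-LBL against the reference gave 0, 100 without arrays on re-used slides, 371 after subtraction of M10 and 0 to 5 with 1 array left out, the highest without M9. Secondary T-LBL against the reference gave 23, 3 with origin as a random block, 9103 with array weights, 36 without arrays on re-used slides, 94 after subtraction of M10, 35 with windows of 5 probes and 5 to 8 with 1 array left out. It gave 0 with normexp signals and 0 with M12.53 turned, with 2015 and 3173 windows at an unadjusted p under 0.05. Primary T-LBL against the myeloid array gave 0, 12 with scan as a block, 40 without arrays on re-used slides and 0 to 4 with 1 array left out, the highest without M9 and 2 without M12. Subtraction of M10 puts the noise of that array into every other, and turning M12.53 makes its losses gains. Without arrays on re-used slides, M12 is the only primary lymphoma. For secondary against primary T-LBL, 3 of the 83 windows then lay in the shared losses, and 1194 windows on X, where the reference dye of M12 deviates, were called beside them. Scan as a block rests on M9 as the only primary array, joined to M10 through the secondary arrays. The other causes were not tested.

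GC regression was not run. Scan as a block was not fitted for the comparisons against the reference, where group and scan levels cannot be told apart. Leaving out calls of M12 that M10 also holds removed 0 of its 7 calls, and asking for 3 probes per window removed nothing. On M7, 53.8% of reference spots were well above background, which limits its ratios.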

Other observations

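The values in this part belong to no comparison, and the choice to report them was made after they were seen.

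M12.53 and M7 showed a probe pattern opposite to that of most arrays. The correlations of M12.53 over autosomal probes were the same to 2 decimals after the density correction with M10 (−0.46) and M12.52 (−0.51). In the chromosome 10 region the log2 ratio of M12.53 was 0.45, and the sample dye deviated by 0.73 and the reference dye by 0.32. After the density correction the ratio was 0.47.

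On the short chromosome 12 loss from 114670169, the reference dye of M12 deviated by −1.09 ± 0.07, while that of the secondary arrays lay between −0.05 and 0.09. The log2 ratio of −0.15 in M12 is therefore not on the same footing as those of the secondary tumours.

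In the chromosome 3 core the sample dye deviated by 2.33 in M7, 2.74 in M9 and 2.95 in M10, and by −0.33 in M12. In the secondary tumours it deviated by −0.00 in M12.49, −1.54 in M12.50, −0.23 in M12.52 and −0.60 in M12.53. M7 also had a reference deviation of 2.30 there, on an array where dim probes were common.

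M9 had a log2 ratio of 0.29 over the whole of chromosome X, with a sample dye deviation of 0.19, and −0.23 on chromosome Y.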
